A study of Arabidopsis thaliana with 6 samples.

How the data were processed

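RNA from light-grown seedlings of Arabidopsis thaliana was measured on 6 Affymetrix ATH1 arrays, which carry short oligonucleotide probe sets for nuclear, chloroplast and mitochondrial genes. The titles put 3 arrays in the wild type group (accession Col-0) and 3 in the VFB mutant group. VFB stands for a small family of F-box proteins related to the auxin receptors TIR1 and AFB. The labels call the plants a triple mutant and do not say which VFB genes carry the mutations. About 80 mg of tissue was extracted per sample and about 6 µg of total RNA was labelled, per the labels' protocols.

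The labels disagree in 2 places. All 6 descriptions give an age of 10 days, whereas the source names and extract protocols of the 3 mutant samples give 5 days. The extract protocol of mutant replicate 3 also names a wild type of accession No-0. Samples were grouped by title, so mutant replicate 3 stayed in the mutant group. Age and genotype cannot be separated if the mutant seedlings were 5 days old.

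The deposited values are probe set intensities on a linear scale. MAS5 made them, per the submitters' processing notes, and its version and settings are not given in the sources used here. Each deposited array had a trimmed mean of 500 after 2% of values were removed at each end, so the intensities had been scaled by 1 factor per array. Array medians ran from 184.6 to 204.2. Values were used as deposited, as log2(value + 16). A fold change on this scale understates the change of dim probe sets. The number of arrays, 3 per group, limits the precision.

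Each array held 22810 probe sets, of which 64 were controls and were left out of the tests. A probe set was tested when its mean log2 value lay above the 40th percentile, which left 13647. Gene names came from the platform annotation given with the data, updated by Entrez number against RefSeq (assembly TAIR10.1). It paired 13513 probe sets with 1 gene, 503 with several and 8730 with none. Of the 13513, 13436 matched a RefSeq gene. Of the tested probe sets, 7325 had 1 gene, and 6043 were unnamed here. Only probe sets with 1 gene are named. No VFB gene had a probe set named here, so the mutated genes were not analysed and the labels could not be checked against them.

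Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples. On simulated data with 200 changed probe sets among 13647, the fit recovered 34% of 1.5-fold changes, 76% of 2-fold changes and 100% of 4-fold changes, with 4 false calls among 159. The real arrays gave 2541 calls, and with more calls the adjustment is less strict. These shares therefore do not give the power of the real comparison.

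Gene lists were tested with limma's camera at a preset correlation of 0.01, for lists with at least 3 tested members, 1 probe set per gene. The design, 27 lists with 364 members, and the alternatives for those lists, the probe sets, the named genes and RNA quality were fixed before the data were examined. Only 60 listed members had a probe set named here, which left 5 lists to test. A further 29 lists, by gene family, were therefore added after the annotation was read and before any fold change was computed, and 27 of them could be tested. Adjustment ran over each collection separately. Families taken by symbol can catch other genes, and the cytochrome P450 list holds 2 cyclophilins, CYP59 and CYP71.

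The named genes followed a rule. They are the 12 largest rises and 12 largest falls among single-gene probe sets past the threshold with no overlap between the groups, and up to 4 called members of each list. RNA quality was compared through 3' to 5' ratios of control probe sets with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. Alternatives were other offsets (1 and 64), quantile normalization, median centring, no filter or a 60th percentile filter, other variance models, other thresholds, a per-probe-set unequal-variance test, a replicate block, leaving out each array, an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9.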

Results

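Seedling RNA was profiled on 6 arrays, 3 from wild type and 3 from the VFB triple mutant, to find which transcripts differ when VFB F-box genes are mutated. Of 22746 gene probe sets, 13647 were bright enough to test. Values below are MAS5 signals as mean ± SD (n = 3 per group) and log2 changes, mutant minus wild type, with their standard errors. In counts of list members, rose and fell mean past the threshold in that direction.

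Among single-gene probe sets past the threshold with no overlap between the groups, the largest rise was in THI2.1. THI2.1 encodes a thionin, a small antimicrobial peptide. Its signal was 43.1 ± 6.29 in wild type and 2351 ± 1890 in the mutant, a log2 change of 4.58 ± 0.733 (limma, adjusted p = 0.00107). AT3G28270 rose 14.4-fold, from 170.1 ± 23.7 to 2790 ± 1030. Among the same probe sets AT5G12050 fell the most, from 1979 ± 227 to 262.0 ± 52.4, a log2 change of -2.85 ± 0.148 (limma, adjusted p = 1.47e-06). IAA29, an Aux/IAA repressor of auxin signalling, went from 436.1 ± 146 to 70.7 ± 14.3, a log2 change of -2.35 ± 0.230.

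Other large rises were in AT1G54020 (log2 change 3.48), AT3G28220 (2.90), AT1G52100 (2.59), which encodes a jacalin-type lectin, AT1G12030 (2.49) and AT2G05540 (2.46). AT4G22470 (2.40), AT1G09500 (2.36), AT1G62510 (2.35) and the defensin-like gene PDF1.4 (2.23) followed. AT4G22470 was at 109.3 in wild type replicate 3, against 347.4 or more in the other wild type arrays. Its lowest log2 change without 1 array was 1.88. AT1G47400, which encodes a small peptide of the iron deficiency response, rose 4.54-fold, from 828.7 ± 95.6 to 3816 ± 394. In mutant replicate 2, THI2.1 was at 228 and AT1G54020 at 157.1, against 2964.4 or more and 1482.3 or more in the other mutant arrays. Without that array their log2 changes were 5.85 and 4.65, and without mutant replicate 1 they were 3.86 and 2.71. With a robust variance model THI2.1 (adjusted p = 0.0802), AT1G54020 (adjusted p = 0.128) and EXO (adjusted p = 0.0787) no longer passed in limma.

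Other large falls were in AT5G62280 (-2.82), AT5G57760 (-2.25), the glutaredoxin gene AT2G47880 (-2.06), AT3G23550 (-2.02), AT3G04210 (-1.97), AT3G59350 (-1.77) and AT4G14060 (-1.69). GH9B13, an endoglucanase of the cell wall, fell from 1234 ± 305 to 352.3 ± 47.0. SP1L2, a relative of the microtubule protein SPIRAL1, changed by -1.63, and EXO, a brassinosteroid-induced gene linked to cell expansion, by -1.58.

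**Figure D1:**
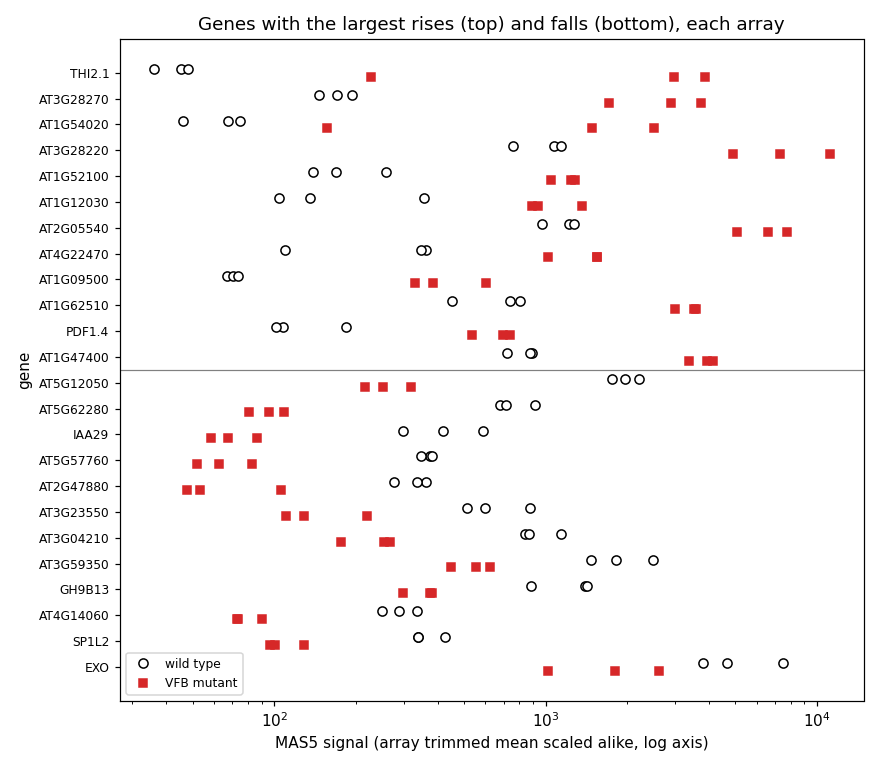
MAS5 signal of each array on a log axis, for the 12 genes with the largest rises (above the line) and the 12 with the largest falls (below it). Open circles are the 3 wild type arrays and red squares the 3 mutant arrays, and in each of these genes the groups do not overlap.

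In all, 2541 of 13647 probe sets passed (18.6%), 1115 higher and 1426 lower in the mutant. No gene was named here for 597 of the higher and 685 of the lower ones. Changes of at least 2-fold were found in 262 of the higher and 218 of the lower ones. The median size of a called change was 0.64 on the log2 scale. The groups did not overlap in 36.1% of tested probe sets, where chance gives 10%. Higher calls made up 43.9% of all calls as deposited and 61.8% after centring each array on its median, so the balance of directions rests on the scaling. An unequal-variance test on each probe set alone called 6.

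Among auxin-related genes, both tested Aux/IAA genes fell, also when adjusted over the list alone. IAA18 changed by -0.37 ± 0.118 (limma, adjusted p = 0.0432), a call lost under quantile normalization (adjusted p = 0.0572) and median centring (adjusted p = 0.14), and without wild type replicate 1 (0.133) or 2 (0.103) or mutant replicate 1 (0.129) or 2 (0.111). The auxin-conjugating genes GH3.3 (-0.31 ± 0.129) and WES1 (-0.03 ± 0.150) did not pass.

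Expansins, which loosen cell walls, were lower as a list (camera adjusted p = 0.0117), but not with an estimated correlation (adjusted p = 0.404). Of 9 tested members 4 fell and 0 rose, and 5 fell when adjusted over the list alone. EXLA1 fell 2.97-fold, from 2498 ± 544 to 845.9 ± 275, and EXLA2 2.89-fold, from 301.6 ± 52.9 to 98.7 ± 46.9. EXPA4 changed by -0.68 ± 0.106 and EXPB3 by -0.59 ± 0.133. Without wild type replicate 2 the list's camera adjusted p was 0.0536. EXPB3 also lost its call without that array (adjusted p = 0.0501).

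Of 5 tested xyloglucan endotransglucosylase/hydrolase genes, only XTH16 passed the threshold, and it was lower (-0.69 ± 0.121), also when adjusted over the list alone. The list's camera adjusted p was 0.972, and its median (0.0945) and mean (-0.104) differ in sign. In the cold and abscisic acid list COR15B fell from 2657 ± 257 to 1158 ± 361 and COR47 from 4501 ± 857 to 2474 ± 496, while COR15A differed by -0.16 ± 0.269. The same 2 of 3 passed when adjusted over the list alone. Camera gave an adjusted p = 0.0423, but adjusted p = 0.367 with an estimated correlation. That call was lost without wild type replicate 1 (adjusted p = 0.0777), wild type replicate 2 (0.0536) or mutant replicate 2 (0.204), and with eBayes without trend (0.0825).

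STZ, a zinc finger repressor induced by stress, rose 2.39-fold and was the called member among 3 tested touch and stress genes, also when adjusted over the list alone (camera adjusted p = 0.187). STZ was at 200.6 in wild type replicate 3, against 373.3 or more in the other wild type arrays. Its lowest log2 change without 1 array was 0.93, against 1.26 with all. The HSP70 gene AT3G09440 rose 2.22-fold, from 951.8 ± 81.4 to 2175 ± 555. DFR, an enzyme of anthocyanin synthesis, rose 2.71-fold over all probe sets, and the second flavonoid gene, UF3GT (1.31 ± 0.492), passed only when adjusted over the list alone. DFR varied from 314.1 to 1398.6 between mutant arrays and did not pass with a robust variance model (adjusted p = 0.166), without filter (adjusted p = 0.0529), or without wild type replicate 2 (adjusted p = 0.0595), mutant replicate 1 (adjusted p = 0.0505) or mutant replicate 3 (adjusted p = 0.0653).

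The root hair peroxidase gene AT4G26010 changed by -1.07 ± 0.253. The root gene PYK10 (0.20 ± 0.118), the photosynthesis genes LHCB4.1 (0.19 ± 0.107) and RCA (0.28 ± 0.104), the cell cycle gene PRL (0.04 ± 0.119) and the clock gene GI (0.29 ± 0.116) did not pass over all probe sets. RCA passed when adjusted over its list of 2 tested genes (limma, adjusted p = 0.0362), but not over the added nuclear photosynthesis list (adjusted p = 0.0798). GI was the 1 tested member of its list, so its limma p of 0.0293 there is unadjusted. AGL24 (-0.37 ± 0.183), PDF1.2 (0.22 ± 0.310) and CSN5B (-0.07 ± 0.189), each the 1 tested member of its list, did not pass by either count. Of 4 reference genes PEX4 was called (-0.34 ± 0.108), also when adjusted over the list alone, and its call was lost under quantile normalization (adjusted p = 0.0566), median centring (adjusted p = 0.147) and without any array but wild type replicate 3. The reference list's camera adjusted p was 0.972, with a median of 0.0544 and a mean of -0.0365. The lateral root, cytokinin, glucosinolate and seed reserve lists had no bright member, and 6 lists had no probe set named here.

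Among the added families, members of the cytochrome P450 list rose. Of 12 tested, 6 rose and 1 fell (7 and 1 adjusted over the list alone). CYP71B26 rose by a log2 change of 1.72, from 333.1 ± 35.8 to 1146 ± 228, CYP71B23 1.88-fold and CYP71B24 1.87-fold, while CYP71B22 changed by -0.86 ± 0.176. These named genes carry close locus numbers, from AT3G26200 to AT3G26290, so they may not count as separate observations. Camera gave an adjusted p = 0.00872, but adjusted p = 0.442 with an estimated correlation. Without the filter the list's median change was 0.0789 (camera adjusted p = 0.0465), against 0.475 with it. The list, taken by gene symbol, also holds the cyclophilins CYP59 and CYP71, and without them 6 of 10 rose and 1 fell (camera adjusted p = 0.00235, but adjusted p = 0.442 with an estimated correlation).

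Of 14 tested serine carboxypeptidase-like genes 7 fell and 0 rose (8 and 0 adjusted over the list alone). SCPL34 fell 2.75-fold, from 1810 ± 374 to 641.5 ± 59.2, and scpl31 2.32-fold, with scpl50 (-0.88) and scpl35 (-0.81) next. Camera gave an adjusted p = 0.0113, but adjusted p = 0.442 with an estimated correlation. The GH9 endoglucanases had 2 called lower of 4 (3 adjusted over the list alone), GH9B13 and GH9B8 (-0.58 ± 0.161). Their camera adjusted p was 0.0293, but adjusted p = 0.442 with an estimated correlation, adjusted p = 0.142 without the filter and adjusted p = 0.054 with the 60th percentile filter. GH9B8 was lost under median centring (adjusted p = 0.0524) and without wild type replicate 1 (0.0823) or 3 (0.0932) or mutant replicate 3 (0.0755). Without the filter the carboxypeptidase list had an adjusted p = 0.0514.

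Class III peroxidases moved both ways. Of 27 tested, 11 fell and 3 rose (12 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.106). AT5G64120 rose 4.13-fold, from 1904 ± 995 to 7041 ± 947, and AT5G39580 4.26-fold, whereas AT1G30870 changed by -1.03 ± 0.226. Without wild type replicate 3 the log2 change of AT5G39580 was 1.45 in place of 2.09. AT5G64120 was at 788.5 in that array, against 2225.1 or more in the other wild type arrays. Its lowest log2 change without 1 array was 1.51. With a robust variance model AT5G39580 (adjusted p = 0.0946) and AT5G64120 (adjusted p = 0.0626) did not pass.

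**Figure D2:**
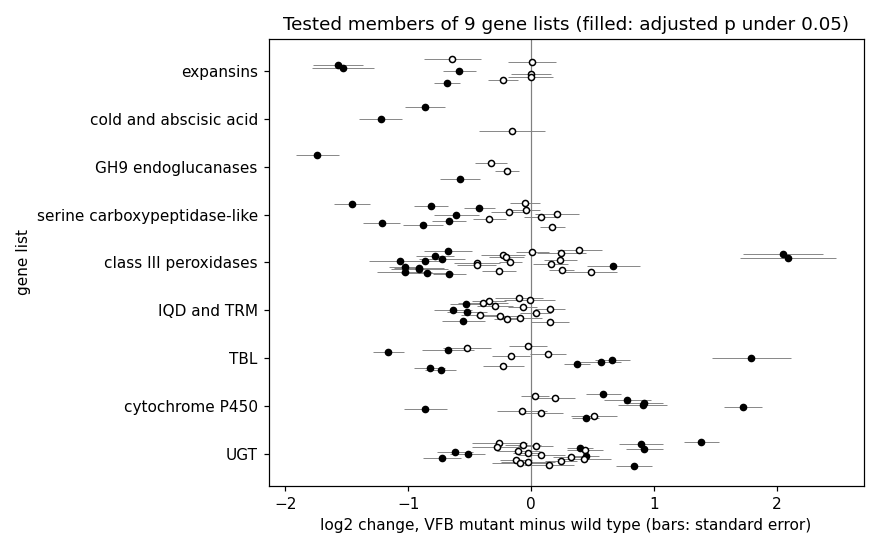
Log2 change, mutant minus wild type, of each tested member of 9 gene lists, with bars for the standard error. Filled points passed the threshold over all probe sets, as in 4 of 9 expansins and 7 of 14 serine carboxypeptidase-like genes, and these lists were picked for the plot after their values were seen.

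Other families had called members without passing as lists. UDP-glycosyltransferases had 6 higher and 3 lower of 24 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0925), led by UGT84A3, which rose 2.61-fold. TBL cell wall proteins had 4 higher and 4 lower of 13 (4 and 5 adjusted over the list alone, camera adjusted p = 0.714), with TBL26 3.46-fold higher and TBL36 2.24-fold lower. SWEET sugar transporters had 2 higher of 8, over all probe sets and over the list alone (camera adjusted p = 0.0925), and SWEET2 rose 2.68-fold. The autophagy list had 4 lower of 10 by both counts (camera adjusted p = 0.106), all in the ATG8 family, and 2 of these 4 passed after median centring. Without wild type replicate 2 APG8A (adjusted p = 0.0539), APG8H (0.0929) and ATG8D (0.0997) lost their calls, and without mutant replicate 2 ATG8E (0.0764), APG8H (0.096) and ATG8D (0.167) did. Without wild type replicate 3 ATG8E (0.0726) and ATG8D (0.163) were lost, and without wild type replicate 1 or mutant replicate 3 APG8H and ATG8D were.

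IQD and TRM genes, linked to microtubules, fell in 4 of 17 by both counts (camera adjusted p = 0.0925), led by IQD22 (-0.64 ± 0.151), and each of these 4 calls was lost without wild type replicate 2 or 3. TRM26 and TRM15 were also lost under quantile normalization (adjusted p = 0.105 and 0.0591) and median centring (adjusted p = 0.0954 and 0.0783). CSLC04, a cellulose synthase-like gene, changed by -0.90 ± 0.165, 1 of 4 tested in its list (3 adjusted over the list alone, camera adjusted p = 0.0925). The peptide gene RALFL22 changed by -1.17 ± 0.176, 1 of 6 by both counts (camera adjusted p = 0.0925). TET10 changed by -0.70 ± 0.138, 1 lower of 7 tetraspanins (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.521). Beta-glucosidases had BGLU33 lower (-1.11 ± 0.116) and BGLU40 higher (0.61 ± 0.136) of 9 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.66). Glutathione transferases had 1 higher and 2 lower of 7 by both counts (camera adjusted p = 0.956), with GSTU16 at 0.80 ± 0.138 and GSTU26 at -0.84 ± 0.187. The other lower call, GSTU22 (-0.48 ± 0.157), was lost under quantile normalization (adjusted p = 0.0807) and median centring (adjusted p = 0.0975), and without any array but wild type replicate 1. UBC22 (-0.38 ± 0.103) was 1 of 11 ubiquitin-conjugating genes by both counts (camera adjusted p = 0.714), a call lost under median centring (adjusted p = 0.0894) and without wild type replicate 1 (0.0724), mutant replicate 1 (0.0578) or mutant replicate 2 (0.0716). VPS20.1 (-0.43 ± 0.125) was 1 of 15 trafficking genes, 0 adjusted over the list alone (camera adjusted p = 0.0925), and was also lost under median centring (adjusted p = 0.0722) and without wild type replicate 2 (0.104) or 3 (0.102) or mutant replicate 2 (0.0763) or 3 (0.0821).

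Of 105 tested cytosolic ribosomal protein genes, 3 were called higher over all probe sets and 0 when adjusted over the list alone. Their median change was 0.0863 as deposited and 0.0125 after quantile normalization, where 1 was called higher and 1 lower, and 0.177 after median centring, where 5 were called higher. Camera gave an adjusted p = 0.0113, but adjusted p = 0.568 with an estimated correlation, 0.812 after quantile normalization and 0.103 without wild type replicate 2. Chloroplast genes moved both ways, with petD (1.95-fold), petN (1.89-fold) and rps14 (2.23-fold) higher and psaA (-0.87 ± 0.163) lower. The call of rps14 was 1 of 19 organelle-encoded ribosomal protein and RNA polymerase genes by both counts (camera adjusted p = 0.235). In that group 2 were higher after quantile normalization and 3 after median centring. The chloroplast photosynthesis list had 2 higher and 1 lower of 33 by both counts (camera adjusted p = 0.0988), 2 higher and 3 lower after quantile normalization, and 4 higher and 1 lower after median centring. In that list petN lost its call without mutant replicate 2 (adjusted p = 0.0555). Among 9 chloroplast NDH genes ndhH fell (-0.53 ± 0.132), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.883), and 2 higher and 1 lower after median centring. That list had a median of -0.0651 while camera gave the direction up, and ndhH was lost without wild type replicate 2 (adjusted p = 0.0716). The mitochondrial genes cox1 (0.61 ± 0.162) and ccb452 (0.52 ± 0.144) rose, 2 of 6 by both counts (camera adjusted p = 0.211), and both were lost without mutant replicate 2 (adjusted p = 0.0863 and 0.0785) or wild type replicate 1 (0.0504 and 0.0774). The call of cox1 was also lost without wild type replicate 3 (0.0764), and that of ccb452 without wild type replicate 2 (0.0595) or mutant replicate 3 (0.0688). PRK, a Calvin cycle enzyme, rose 1.34-fold, 1 of 12 nuclear photosynthesis genes by both counts (camera adjusted p = 0.135), and was lost under quantile normalization (adjusted p = 0.0875), without the filter (0.0555), and without wild type replicate 1 (0.0681) or mutant replicate 2 (0.0662). Histone, proteasome, ubiquitin protease, U-box and MADS-box lists had 0 called members as deposited. After median centring 1 of 12 ubiquitin proteases was called higher.

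The arrays separated by group, which follows the genotype and also the age in the source names. Correlations of log2 values across tested probe sets were 0.9779 to 0.9852 between wild type arrays, 0.9779 to 0.9803 between mutant arrays and 0.9405 to 0.9563 between the groups. The first principal component held 60.2% of the variance and parted the groups. Mutant replicate 3, whose extract protocol names another plant, lay with the other mutant arrays. Genes do not stand for independent replicates in these correlations.

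RNA quality was compared through the actin, GAPDH and ubiquitin controls. The 3' to 5' ratio of actin was 2.80 ± 0.231 in wild type and 3.4 ± 0.188 in the mutant (n = 3 each, exact permutation p = 0.1, the smallest possible), higher in every mutant array. GAPDH gave 1.13 ± 0.0577 and 1.13 ± 0.0836 (exact permutation p = 1), and ubiquitin 1.45 ± 0.101 and 1.64 ± 0.227 (exact permutation p = 0.3). The older control sets gave 19.0 ± 6.52 and 25.8 ± 3.25 for actin (exact permutation p = 0.1), also higher in every mutant array. They gave 2.23 ± 0.183 and 2.38 ± 0.262 for GAPDH (exact permutation p = 0.6), and 3.03 ± 0.238 and 3.80 ± 0.555 for ubiquitin (exact permutation p = 0.2).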

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

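Control probe sets lay outside the tests of genes, and all 5 of those for Arabidopsis GAPDH, a glycolytic enzyme, were higher in every mutant array than in every wild type array. In a fit that included the controls 3 of the 5 passed. The newer 5' set was 1.39-fold higher, from 6780 ± 135 to 9412 ± 343 (limma, n = 3 per group, adjusted p = 0.0111). The newer 3' set was 1.38-fold higher (adjusted p = 0.0249) and an older middle set 1.27-fold higher (adjusted p = 0.0353). The older 3' set (1.22-fold, adjusted p = 0.12) and the older 5' set (1.14-fold, adjusted p = 0.263) did not pass. After quantile normalization the newer 5' set still passed (1.28-fold, adjusted p = 0.0308) and the newer 3' set (1.29-fold, adjusted p = 0.0681) and the middle set (1.22-fold, adjusted p = 0.0642) did not. After median centring these 3 passed, the newer 5' set at 1.48-fold (adjusted p = 0.00681), the newer 3' set at 1.47-fold (adjusted p = 0.013) and the middle set at 1.36-fold (adjusted p = 0.0177).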

How the results depend on the processing

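Alternatives for the added lists, for the array similarity and for the P450 list without its cyclophilins were chosen after seeing the data. The count of 2541 called probe sets was 2537 and 2562 with offsets 1 and 64, 2381 after quantile normalization and 2516 after median centring, where the split was 1556 higher and 960 lower. All 2541 kept their sign wherever they were still tested. Filters, variance models and the replicate block leave the log2 change unchanged, so only offsets, scalings and left-out arrays could have reversed a sign. Stricter rules left 480 at 2-fold (262 higher, 218 lower) and 1225 at adjusted p 0.01 (581 higher, 644 lower). The unequal-variance test on each probe set alone left 6 (2 higher, 4 lower), with 2946 at an unadjusted p under 0.05; the cause of that fall was not tested. Leaving out 1 array gave 1694 to 2265 calls, 782 to 975 higher and 878 to 1290 lower.

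Of the planned lists 2 passed, 1 with eBayes without trend (the cold and abscisic acid list was lost), 0 with an estimated correlation and 0 to 2 without 1 array. Of the added lists 4 passed, 0 with an estimated correlation, 12 with fry, which does not compare a list with other genes, and 4 to 7 without 1 array. Estimated correlations were 0.326 for expansins, -0.0895 for the cold and abscisic acid list and 0.048 to 0.118 for the 4 added lists. The cold and abscisic acid list lost its call with an estimate below the preset 0.01. That setting therefore differs from the main one in more than the correlation. Beyond this, the cause of the changed list counts was not tested. The P450 list without its 2 cyclophilins had 6 of 10 members higher and 1 lower, with a camera adjusted p of 0.00235, and 0.442 with an estimated correlation. Named genes were refitted under other offsets, scalings, filters and variance models, with the replicate block and without each array, but not under other thresholds or the unequal-variance test. Of 88, 59 kept their call in each of these fits that tested them, 29 lost it in at least 1, and 0 reversed. A reversal was possible only with other offsets or scalings or a left-out array. The actin ratio differed by 0.6 for 3' to 5' and by 0.09 for middle to 5'. Each of the 6 arrays was closest to one of its own group in every setting that kept all arrays.

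Replicate numbers do not pair the arrays: deviations of arrays with the same number correlated at -0.196, 0.0157 and -0.167. Arrays with different numbers correlated at -0.0377 to 0.194. The highest were wild type replicate 3 with mutant replicate 1 (0.194) and wild type replicate 1 with mutant replicate 3 (0.183). Whether the groups share a batch or order in another pairing was not tested. With the replicate block, 1988 probe sets and the same numbers of lists, 2 and 4, passed. The VFB genes had no probe set named here, so their alternatives were not run.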

Other observations

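The tests of time of day and of age, and the fit without filter for seed genes, were chosen only after related values had been seen. No seed maturation gene passed the brightness filter, so 20 of them were examined without it. M17, a late embryogenesis gene, went from 18.1 ± 20.9 to 310 ± 62.9 (log2 change 3.41 ± 0.386, limma, adjusted p = 0.000603). AT4G36700, a cupin-family gene, went from 27.4 ± 37.9 to 354 ± 89.8 (adjusted p = 0.00218). Of the 20, 6 were higher in every mutant array and 0 lower in every mutant array, but only these 2 passed. ICL, of the glyoxylate cycle that uses seed oil, was at 16.5 ± 18.1 and 60.4 ± 18.5 (adjusted p = 0.0615), and PAP85 at 31.7 ± 14.1 and 72.1 ± 22.9 (adjusted p = 0.124).

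IAA29, EXLA1 and GH9B13 were lower in the mutant. Younger mutant seedlings, as their source name reads, may account for this, and 2 seed maturation genes had a mean signal of 100 or more in the mutant, where 5 had been set as the number needed to decide. Another time of harvest may also account for it. The median change of morning clock genes was -0.00993 from 1 tested gene, and that of evening genes -0.454 from 3. Of these COR27 fell (-0.89 ± 0.142, adjusted p = 0.00105), while GI went the other way (0.29 ± 0.116, adjusted p = 0.111). Age, time of day and genotype cannot be told apart here. The labels disagree on the age of the mutants, an age of 5 days would follow the genotype, and too few clock genes were tested.

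It may be that mutant array 3 is a wild type of another accession, as its extract protocol reads. That would set many transcripts on it apart, yet 0 tested probe sets on it lay at least 4-fold from both other mutant arrays, against 4 on mutant replicate 2 and 0 on mutant replicate 1. The value argues against this array alone being another genotype. Whether all mutant arrays share another background is not settled by it.

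Strongly changed genes, those called with at least 2-fold change, may gather in chromosome segments of another accession in the mutant. The largest number among 50 tested neighbours was 9, on chromosome 1 from AT1G50320 to AT1G52200, 8 higher and 1 lower, against a 95th percentile of 8 and a 99th of 9 in 1000 random placements (permutation p = 0.014). Neighbours there include AT1G51820, AT1G51850 and AT1G51860, and with runs of adjacent genes counted once the largest number was 7 (permutation p = 0.191), so this stays open. Around the VFB genes the largest number was 2, below the 95th percentile of 4 for all windows. No gathering was therefore seen among the 50 tested neighbours of each. Longer segments linked to these genes cannot be judged from such short windows, and the labels do not say which VFB genes are mutated. VFB1 (AT1G47056) lies on chromosome 1, as does the stretch with 9.

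Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many called probe sets, the real one with 2541, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05.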
